A study of Mus musculus with 12 samples.

How the data were processed

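RNA was sequenced from enriched cortical neurons of mice at postnatal day 1 (P1) and postnatal day 14 (P14). Per the labels' protocols, animals with floxed Zmiz1 alleles (Zmiz1f/f) served as wildtype and animals that also carried Cre recombinase at Emx1 (Zmiz1f/f;Emx1Cre) as knockout, and the libraries were made with the TruSeq RNA kit, version 2. Each of the 4 groups (2 ages by 2 genotypes) had 3 libraries. The labels do not say whether a library came from 1 animal or a pool, how neurons were enriched, or which Zmiz1 exons are floxed.

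The authors deposited 1 table of gene values per age. The deposited values are a signal that is never negative, namely gene counts scaled between the 6 libraries of a table, and their build is mm10 per the submitters' processing notes. The aligner, the read counter and their settings are not given in the sources used here, nor is it stated whether counting used strand. The tables held 24972 gene symbols, of which 24490 matched the GENCODE M21 annotation used for identifiers and positions. Low values of a library lay near multiples of a single step but not exactly on them, so whole reads were not recovered and no count test was run. The design had foreseen either raw counts or normalised values, and the branch for normalised values was used. Dividing each library's total by the value of its step gave approximate depths of 3.20 to 7.87 M reads.

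Values were tested with limma 3.58.1 (with trend) in R 4.3.3 on log2(value + 1), for genes with a mean value of at least 10 over the libraries of the fit. P values were adjusted by the method of Benjamini and Hochberg, with 0.05 as the threshold. A fold change is therefore on the log2(value + 1) scale, which understates the change of low genes. Errors beside values are the SD between libraries of a group, errors of log2 fold changes are the SE from limma, and intervals are at the 95% level. Each age was fitted on its own 6 libraries. The difference between the knockout effects at P14 and P1 was tested as a contrast in a fit of all 12 libraries, in which a factor common to a table cancels. P14 and P1 wildtype libraries were not tested against each other, since the tables were scaled separately.

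Before the data were examined, 58 gene lists were written from textbook knowledge. Those with at least 5 measured members were tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison; camera with an estimated correlation and fry were alternatives. For each list, members that passed were counted over all genes tested and again adjusted over the list alone. Named genes followed a rule written at the same time. It took Zmiz1, the 8 largest changes each way among passing genes whose groups did not overlap, and up to 4 members of smallest p from each list called by camera or marking another cell type. For the difference between ages it took the 5 largest each way. Sex-linked genes and unnamed gene models were left out of the largest changes. Zmiz2 came from the fixed list of Zmiz1 relatives. Emx1, Mbp and the genes shared between the calls at both ages were named after their values were seen.

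The procedure was tested on simulated data with known changes. For the P1 comparison (13900 genes), 77.6% of genes planted at a log2 change of 0.585 and 100% of those at 1 were recovered, and 4 of the 189 genes called were unchanged ones. For P14 (14080 genes) the shares were 73.1% and 97.0%, with 13 unchanged genes among 193. For the difference between ages (14189 genes) they were 43.3% and 83.1%, with 11 unchanged genes among 309. Of 500 random lists with no shift, 2.40% had a camera p under 0.05. Genes were simulated independently of each other, each with the spread typical of its mean value. Changes were planted only in genes of higher mean value. These shares therefore do not describe low genes, genes with a spread of their own, or lists whose members vary together.

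Alternatives were TMM scaling, no filter and a stricter filter on low values, limma without trend, pseudocounts of 0.1 and 10, the replicate number as a block, and leaving out each library in turn. Others, added after the data were seen, were 1 fit of all 12 libraries for the knockout comparisons, limma-voom on approximate reads, the share of male cells as a covariate, the mean of the myelin list as a covariate, leaving out 2 myelin-rich P14 libraries, scaling to the pan-neuronal list, and thinning of reads. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.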

Results

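The data were normalised read counts of genes in 12 RNA-seq libraries of enriched cortical neurons, 3 for each of wildtype and knockout mice at P1 and at P14. Zmiz1 encodes a transcriptional coactivator related to the PIAS family of SUMO ligases, and Emx1Cre drives recombination in the progenitors of cortical excitatory neurons and of cortical astrocytes. Approximate depths were 5.93 to 7.87 M reads in P1 wildtype, 6.60 to 7.44 M in P1 knockout, 6.03 to 6.50 M in P14 wildtype and 3.20 to 5.66 M in P14 knockout libraries. Pearson correlations of log2 values between libraries of a group were 0.971 to 0.982 in P1 wildtype, 0.975 to 0.981 in P1 knockout, 0.966 to 0.975 in P14 wildtype and 0.947 to 0.963 in P14 knockout. Between the groups they were 0.968 to 0.976 at P1 and 0.911 to 0.959 at P14.

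The targeted gene was not lower in the libraries labelled knockout. Zmiz1 (ENSMUSG00000007817.15, mm10 chromosome 14, 25459185 to 25666743) had normalised counts of 8128, 7474 and 7875 in the P1 wildtype libraries and 7767, 8754 and 8325 in the P1 libraries labelled knockout. The log2 fold change at P1 was 0.08 (SE 0.07, 95% interval -0.07 to 0.23, limma adjusted p = 0.740). At P14 the counts were 3855, 3830 and 3311 in wildtype and 4113, 3913 and 4036 in libraries labelled knockout, with a log2 fold change of 0.14 (SE 0.10, 95% interval -0.09 to 0.37, limma adjusted p = 0.410). The floxed exons are not given in the labels, so a total over the whole gene neither checks the deletion nor the labels, and the groups below are called by their labels. Zmiz2, the closest relative of Zmiz1, fell at P14 from 1845 ± 4.25 to 1460 ± 86.1 (SD, n = 3 per group; log2 fold change -0.34, limma adjusted p = 0.0492, but 0.79 when libraries were scaled to the pan-neuronal list). Emx1, the gene at which Cre is expressed, was at 190 ± 49.1 in P1 wildtype and 104 ± 18.6 in P1 libraries labelled knockout (log2 fold change -0.85, limma adjusted p = 0.133).

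**Figure D1:**
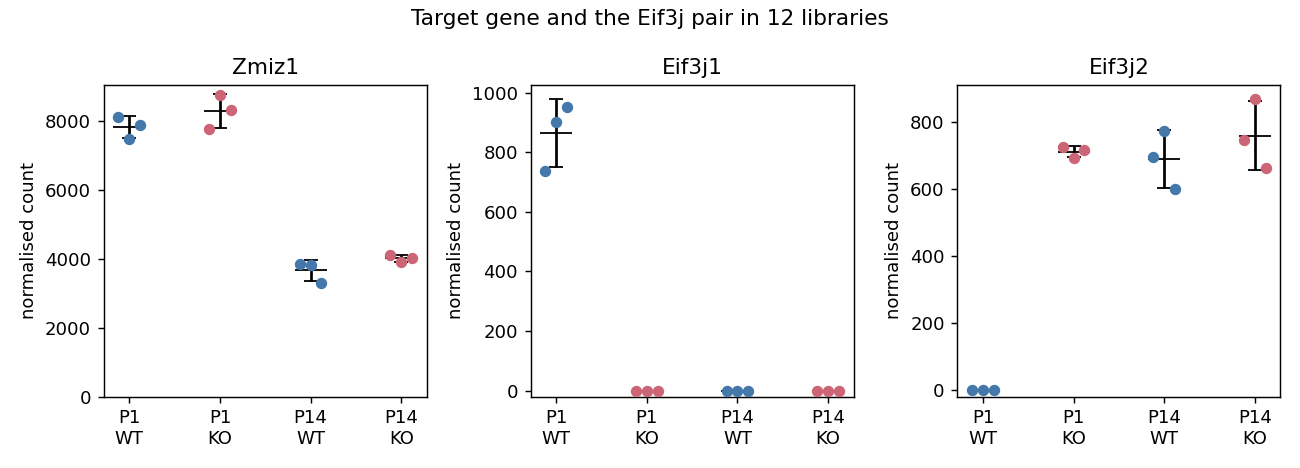
Normalised counts of Zmiz1, Eif3j1 and Eif3j2 in the 12 libraries by age and genotype label; points are libraries, horizontal lines the group means and bars the SD (n = 3). Zmiz1 lies between 7474 and 8754 at P1 in both genotypes, while Eif3j1 and Eif3j2 are listed at 0 in opposite P1 groups.

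The P1 comparison asked which genes differ between genotypes in newborn cortical neurons. Neurog2, Tbr1 and Slc17a6, genes of the glutamatergic lineage, fell in the P1 libraries labelled knockout. Neurog2, a proneural transcription factor of cortical progenitors (chromosome 3, 127633135 to 127635631), fell from 292 ± 34.4 to 117 ± 6.82 normalised counts (SD, n = 3 per group; log2 fold change -1.31, SE 0.15, limma adjusted p = 0.00913). Tbr1, a transcription factor of early-born deep-layer neurons, fell from 2750 ± 419 to 1688 ± 113 (log2 fold change -0.69, SE 0.10, limma adjusted p = 0.0338). Slc17a6, the vesicular glutamate transporter VGLUT2, fell from 1311 ± 218 to 825 ± 40.4 (log2 fold change -0.66, SE 0.11, limma adjusted p = 0.0357). Hes5, a Notch effector that keeps progenitors undifferentiated, rose from 246 ± 61.0 to 500 ± 52.7 (log2 fold change 1.04, SE 0.16, limma adjusted p = 0.0356).

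**Figure D2:**
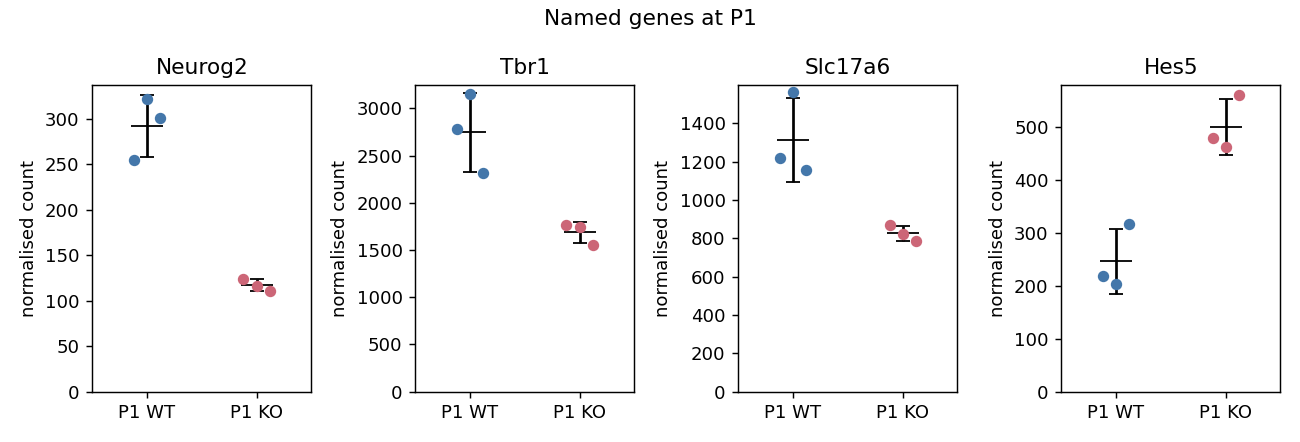
Normalised counts of Neurog2, Tbr1, Slc17a6 and Hes5 in the P1 libraries; points are libraries, horizontal lines the group means and bars the SD (n = 3). The libraries of the groups do not overlap for any of these genes, and Neurog2 falls from a mean of 292 to 117.

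Of 14 pan-glutamatergic genes measured at P1, 3 fell and 0 rose over all genes tested, and 7 fell and 2 rose adjusted over the list alone. The median log2 fold change was -0.36 (camera adjusted p = 0.000472, but adjusted p = 0.647 with an estimated correlation). Neurog2, Tbr1 and Slc17a6 were the members that fell, while Camk2a was at 0.77 (limma adjusted p = 0.110). Of 9 intermediate progenitor genes, Neurog2 and Sstr2 fell (Sstr2 log2 fold change -0.76, limma adjusted p = 0.0272), 7 did not pass, and 1 rose and 3 fell adjusted over the list alone. Eomes, the defining gene of that cell type, was at -0.65 (limma adjusted p = 0.0635), and camera did not call the list (adjusted p = 0.247). The upper-layer list had a median of 0.02 and was not called (camera adjusted p = 0.526), with 2 genes rising and 6 falling adjusted over the list alone. Of 20 deep-layer genes, Tbr1 fell and 19 did not pass, 2 rose and 2 fell adjusted over the list alone, and the median was 0.18 (camera adjusted p = 0.0207, but adjusted p = 0.647 with an estimated correlation).

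Among 45 semaphorin, slit and netrin pathway genes at P1, 3 fell and 0 rose over all genes tested, 14 fell and 4 rose adjusted over the list alone, and the median was -0.11 (camera adjusted p = 0.00255, but adjusted p = 0.647 with an estimated correlation). Unc5a, a netrin receptor, fell by 0.76 on the log2 scale (limma adjusted p = 0.0356), Sema3c by a log2 fold change of -0.67 (limma adjusted p = 0.0356) and Sema5a by -0.59 (limma adjusted p = 0.0457). Wnt7b, a Wnt ligand, fell (log2 fold change -0.62, limma adjusted p = 0.0356) and was the only one of 31 Wnt pathway genes to pass over all genes, with 3 falling adjusted over the list alone (median -0.11, camera adjusted p = 0.0409, but adjusted p = 0.647 with an estimated correlation). Among 30 interneuron genes, Lhx6, a transcription factor of interneurons from the medial ganglionic eminence, rose (log2 fold change 0.55, limma adjusted p = 0.0423) and Sp8 fell (-0.64, limma adjusted p = 0.0357). Adjusted over the list alone, 6 interneuron genes rose and 1 fell (median 0.14, camera adjusted p = 0.0418, but adjusted p = 0.647 with an estimated correlation).

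The pan-neuronal, neuronal maturation and presynaptic lists had positive medians at P1, with 0 members passing over all genes tested. Their library means overlapped between the groups: relative to wildtype they were 0.036, 0.012 and 0.034 in library 3 labelled knockout, within the wildtype range, and 0.35, 0.40 and 0.36 in library 1. The means of the deep-layer, interneuron and Wnt lists overlapped too. Of 20 pan-neuronal genes, 0 passed over all genes and 5 rose adjusted over the list alone, with a median of 0.16 (camera adjusted p = 0.000226, but adjusted p = 0.647 with an estimated correlation). Of 30 neuronal maturation genes, 0 passed over all genes, 5 rose and 1 fell adjusted over the list alone, and the median was 0.24 (camera adjusted p = 0.000472, but adjusted p = 0.647 with an estimated correlation). Syt1, a calcium sensor of synaptic vesicles, was at 0.50 (limma adjusted p = 0.135). In the presynaptic list of 37 genes, 7 rose and 2 fell adjusted over the list alone and 0 over all genes (median 0.21, camera adjusted p = 2.74e-05, but adjusted p = 0.647 with an estimated correlation). Of 16 striatal genes, Foxp1 rose over all genes (log2 fold change 0.50, limma adjusted p = 0.0356) and 7 rose adjusted over the list alone (median 0.34, camera adjusted p = 8.17e-06, but adjusted p = 0.647 with an estimated correlation).

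Endothelial markers moved together at P1. Of 21 endothelial genes, 0 passed over all genes tested and 21 fell adjusted over the list alone, with a median of -0.47 and quartiles of -0.52 and -0.43 (camera adjusted p = 1.50e-12, but adjusted p = 0.647 with an estimated correlation). Abcb1a, an efflux pump of the blood-brain barrier, was at -0.54 (limma adjusted p = 0.0564). Of 10 erythroid genes, 0 passed either way, and the median was -0.67 (camera adjusted p = 0.0148, but adjusted p = 0.647 with an estimated correlation). The erythroid list means of the P1 groups overlapped. Astrocyte genes had a median of 0.15 and were not called (camera adjusted p = 0.392).

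The other named P1 genes that rose were Tox2 (log2 fold change 0.88), Trank1 (0.85), Lrrc4c (0.69), Ephb3 (0.67), Ptprt (0.65) and Tyro3 (0.62), with limma adjusted p from 0.0356 to 0.0478. Those that fell were Eya1 (-0.98), Masp1 (-0.83), Grid2ip (-0.80), Zfp433 (-0.79) and Selenop (-0.77), with limma adjusted p from 0.0232 to 0.0435. Selenop, which encodes a plasma selenium carrier, fell from 11064 ± 1060 to 6531 normalised counts on average. Eif3j1 was listed at 737, 902 and 954 in the P1 wildtype libraries and at 0 in the 3 P1 libraries labelled knockout. Eif3j2 was listed at 0 in the P1 wildtype libraries and at 725, 692 and 717 in those labelled knockout (limma adjusted p = 4.63e-08 for each gene). Of the 75-base sequences of Eif3j2, 87.4% also occur in Eif3j1, and 37.7% of those of Eif3j1 occur in Eif3j2, so the assignment of reads between them is uncertain.

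In all, 41 of 13894 genes passed at P1, 13 higher and 28 lower, and 1558 had an unadjusted p under 0.05. The groups did not overlap for 2136 genes, against a chance share of 10%. Of 55 lists, camera called 24, and 0 of these were called with an estimated correlation (lowest adjusted p = 0.647) or by fry. The count of 41 rests on few libraries: without wildtype libraries 1, 2 and 3 in turn it was 15, 14 and 26, and without libraries 1, 2 and 3 labelled knockout 6, 9 and 139. It was 2 with limma without trend and 2 with all 12 libraries in 1 fit. The excess of lower genes was not kept either. There were 72 higher and 67 lower without library 3 labelled knockout, and 7 and 8 without wildtype library 1.

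At P14 the comparison asked the same of more mature neurons. Neuronal genes were lower in the P14 libraries labelled knockout. Syt1 fell from 4385 ± 456 to 1116 ± 129 normalised counts (SD, n = 3 per group; log2 fold change -1.97, SE 0.12, limma adjusted p = 0.000630). Slc17a7, the vesicular glutamate transporter VGLUT1, fell from 2613 ± 538 to 706 ± 28.04 (log2 fold change -1.87, SE 0.14, limma adjusted p = 0.000630). Penk, which encodes the enkephalin precursor, fell from 1474 ± 191 to 356 ± 65.4 (log2 fold change -2.05, SE 0.16, limma adjusted p = 0.000630). Gad1, a GABA-synthesising enzyme, fell from 2791 ± 543 to 1536 ± 244 (log2 fold change -0.85, SE 0.16, limma adjusted p = 0.0164; it was 0.27 when libraries were scaled to the pan-neuronal list).

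Of 20 pan-neuronal genes at P14, 15 fell and 0 rose over all genes tested, and 16 fell adjusted over the list alone, with a median log2 fold change of -1.22 (camera adjusted p = 3.76e-13, but adjusted p = 0.184 with an estimated correlation). Snap25 (log2 fold change -1.69), Nefm (-1.84) and Eno2 (-1.74) were among them, each with a limma adjusted p of 0.000630. Of 32 neuronal maturation genes, 24 fell and 27 fell adjusted over the list alone (median -1.50, or -0.38 with 5 higher and 14 lower when scaled to the pan-neuronal list; camera adjusted p = 1.50e-18, but adjusted p = 0.128 with an estimated correlation). Among 27 immature neuron genes, Tubb3 (-0.55, limma adjusted p = 0.0189; 0.58 when scaled to the pan-neuronal list) and Crmp1 (-0.58, limma adjusted p = 0.0315; 0.54 when scaled) fell, Nrp1 rose (0.56, limma adjusted p = 0.0459), and 7 fell and 1 rose adjusted over the list alone. The immature list had a median of -0.38, which was 0.74 when scaled to the pan-neuronal list (camera adjusted p = 0.00384, but adjusted p = 0.489 with an estimated correlation).

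Receptor and channel genes were lower too at P14. Of 58 potassium channel genes, 33 fell and 0 rose over all genes tested, and 42 fell and 2 rose adjusted over the list alone (median -1.14, or -0.028 with 9 higher and 11 lower when scaled to the pan-neuronal list; camera adjusted p = 1.27e-17, but adjusted p = 0.128 with an estimated correlation). Kcnj4 fell by 2.19 on the log2 scale (limma adjusted p = 0.000734) and Kcnb1 fell by 1.37 (limma adjusted p = 0.000711). Of 17 GABA and glycine receptor genes, 13 fell and 15 fell adjusted over the list alone (median -1.61, or -0.49 with 3 higher and 8 lower when scaled; camera adjusted p = 3.87e-12, but adjusted p = 0.128 with an estimated correlation), Gabra1 among them (-1.99, limma adjusted p = 0.000630). Of 27 ionotropic glutamate receptor genes, 15 fell and 21 fell adjusted over the list alone (median -1.18, or -0.059 with 8 higher and 5 lower when scaled; camera adjusted p = 3.10e-12, but adjusted p = 0.128 with an estimated correlation), with Grin1 at -1.90 and Grin2b at -1.44 (limma adjusted p = 0.000630 for both). In the presynaptic list of 38 genes, 21 fell and 28 fell adjusted over the list alone, with a median of -0.96, which was 0.16 when scaled to the pan-neuronal list (camera adjusted p = 3.76e-13, but adjusted p = 0.128 with an estimated correlation). Camk2a, a kinase of excitatory synapses, was at -0.34 (limma adjusted p = 0.416), or 0.78 when scaled (limma adjusted p = 0.0167).

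Marker lists of several kinds of neuron shared the lower values. Of 14 pan-glutamatergic genes at P14, 8 fell and 10 fell adjusted over the list alone, with a median of -0.92, or 0.18 when scaled to the pan-neuronal list (camera adjusted p = 1.35e-06, but adjusted p = 0.128 with an estimated correlation). Satb2, a transcription factor of callosal neurons, fell by 1.63 on the log2 scale (limma adjusted p = 0.00103). Of 20 deep-layer genes, 9 fell and 0 rose over all genes, and 12 fell and 1 rose adjusted over the list alone, with a median of -0.88, or 0.24 when scaled to the pan-neuronal list (camera adjusted p = 6.84e-06, but adjusted p = 0.128 with an estimated correlation). Thy1 (-1.69) and Pcp4 (-1.64) were among these, each with a limma adjusted p of 0.000725. Of 20 upper-layer genes, 6 fell and 7 fell adjusted over the list alone, with a median of -0.56, or 0.56 when scaled to the pan-neuronal list (camera adjusted p = 0.000203, but adjusted p = 0.402 with an estimated correlation).

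Lists of GABAergic and striatal markers, named after neurons that arise outside the Emx1 lineage, were lower at P14 as well. The lists do not tell which neurons of these cortical libraries the transcripts came from. Of 31 interneuron genes, 9 fell and 0 rose over all genes, and 18 fell adjusted over the list alone, with a median of -0.75, or 0.37 when scaled to the pan-neuronal list (camera adjusted p = 3.66e-08, but adjusted p = 0.313 with an estimated correlation). Cck (log2 fold change -1.78, limma adjusted p = 0.00185), a neuropeptide gene also used by excitatory neurons, and Slc6a1 (-0.82, limma adjusted p = 0.00773; 0.31 when scaled), a GABA transporter that astrocytes also use, were among them. Of 17 striatal genes, 11 fell and 0 rose over all genes, and 13 fell and 1 rose adjusted over the list alone (median -1.40, or -0.29 with 5 higher and 5 lower when scaled; camera adjusted p = 2.37e-07, but adjusted p = 0.128 with an estimated correlation). Drd1 (-2.11, limma adjusted p = 0.000725) and Ppp1r1b (-1.95, limma adjusted p = 0.00135) fell. Of 22 neuropeptide genes, 9 fell and 16 fell adjusted over the list alone (median -1.62, or -0.54 with 0 higher and 4 lower when scaled; camera adjusted p = 2.08e-10, but adjusted p = 0.184 with an estimated correlation).

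**Figure D3:**
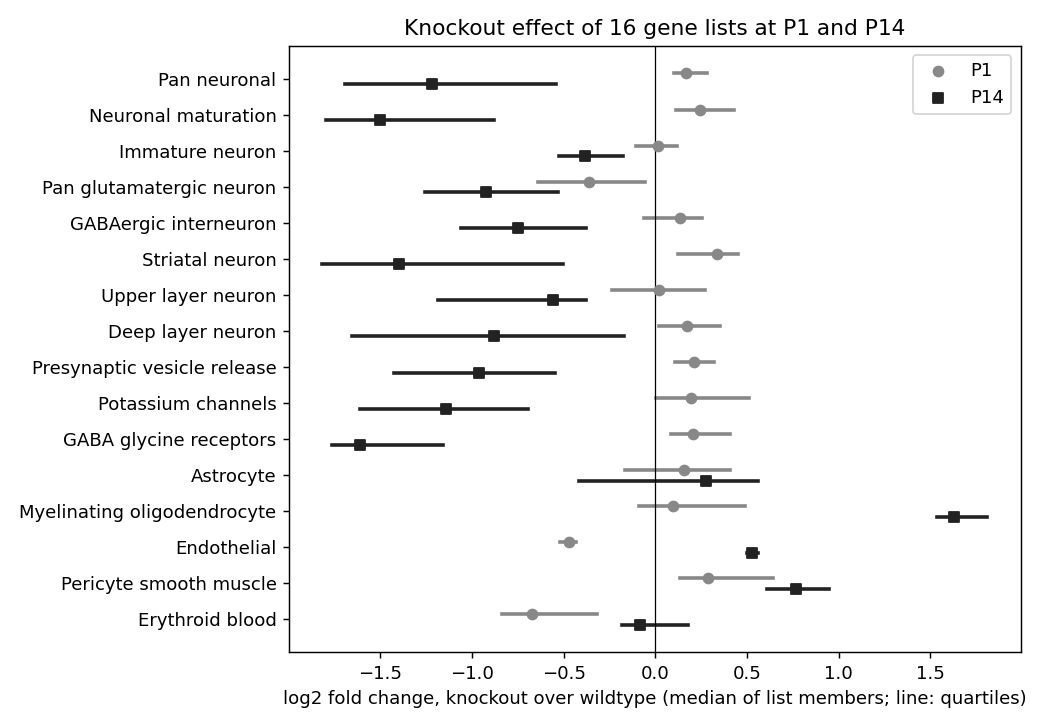
Median log2 fold change, libraries labelled knockout over wildtype, of 16 gene lists at P1 (grey circles) and P14 (black squares); lines span the quartiles of the list members. The pan-neuronal median is 0.16 at P1 and -1.22 at P14, and the endothelial median is -0.47 at P1 and 0.53 at P14, on the scale of the deposited values (scaling to the pan-neuronal list moves the median of all P14 genes to 1.12 and puts the immature, pan-glutamatergic, interneuron, upper-layer, deep-layer, presynaptic and erythroid medians above 0).

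Markers of other cell types varied between the P14 libraries. Of 21 endothelial genes, Slco1a4 rose over all genes tested (log2 fold change 0.69, limma adjusted p = 0.0360) and 20 rose adjusted over the list alone (median 0.53, camera adjusted p = 2.37e-07, but adjusted p = 0.473 with an estimated correlation). Of 21 myelinating oligodendrocyte genes, 0 passed either way although the median was 1.63 (camera adjusted p = 0.000130, but adjusted p = 0.560 with an estimated correlation). The myelin list means relative to wildtype were 2.49, 2.79 and -0.38 in libraries 1, 2 and 3 labelled knockout, and -0.76, 0.95 and -0.19 in wildtype. Mbp, a major myelin protein gene, had 65458, 70110 and 5549 normalised counts in the libraries labelled knockout and 6399, 18276 and 5364 in wildtype. Without libraries 1 and 2 labelled knockout, which leaves a single library of that label, the myelin and cholesterol synthesis lists changed direction. The pan-neuronal list means were -1.06, -1.20 and -1.11 in the libraries labelled knockout and 0.10, -0.21 and 0.11 in wildtype, so that the library with little myelin had them as low. Of 11 MHC class I genes, H2-T22 rose (0.93, limma adjusted p = 0.0117) and 3 rose adjusted over the list alone (median 0.36, camera adjusted p = 0.00384, but adjusted p = 0.437 with an estimated correlation). Of 23 astrocyte genes, Slc1a2, a glutamate transporter, fell (-1.11, limma adjusted p = 0.0206; 0.012 when scaled to the pan-neuronal list), and the list was not called (median 0.28, camera adjusted p = 0.355).

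**Figure D4:**
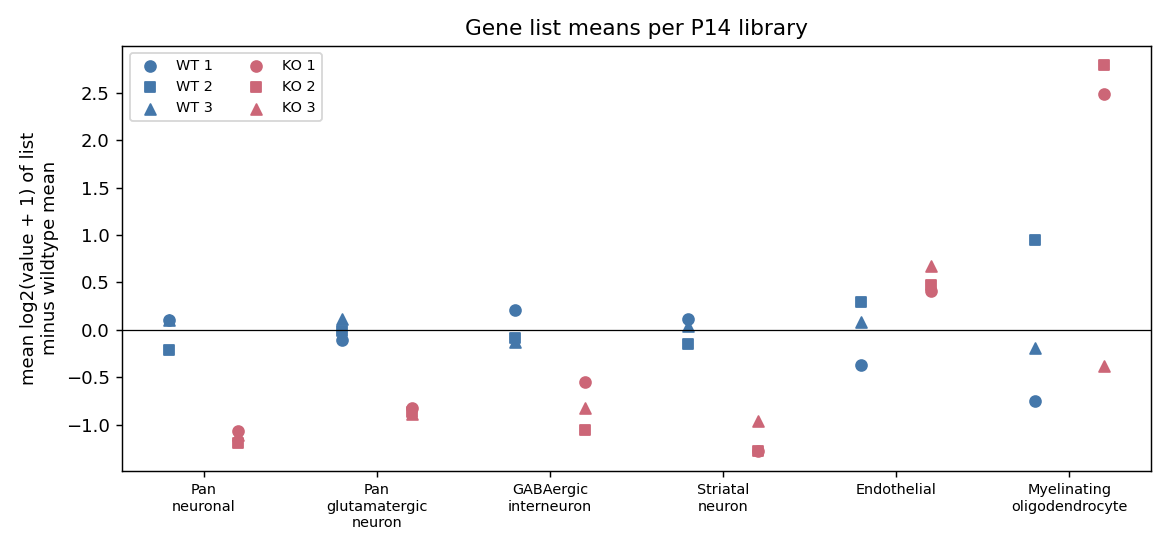
Mean log2(value + 1) of 6 gene lists in each P14 library, minus the wildtype mean; symbols mark the replicates. The 3 libraries labelled knockout lie below wildtype in the pan-neuronal list (-1.06, -1.20 and -1.11), while 2 of them have high myelin means (2.49 and 2.79).

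The named P14 genes with the largest rises were Mcam (719 ± 188 to 1738 ± 610 normalised counts, log2 fold change 1.24, limma adjusted p = 0.0350), an adhesion molecule of vascular cells, then Ppm1j (1.10), Apod (1.10), Cd82 (1.08), Hapln3 (1.08), Fgfbp1 (1.04), Sept4 (1.01) and Tmcc3 (1.01), with limma adjusted p from 0.0347 to 0.0492. Oxtr, the oxytocin receptor gene, fell to 0, 5.17 and 9.09 in the libraries labelled knockout (log2 fold change -3.36, limma adjusted p = 0.0458). As 1 of these is at 0, the size depends on the pseudocount (-4.55 with 0.1, where it did not pass, and -1.80 with 10). The largest falls with values above 0 were those of Pde1a (-2.60, 0.000760), Cckbr (-2.59, 0.00272), Acvr1c (-2.51, 0.0375), Nts (-2.51, 0.00844) and Hbb-bs (-2.48, 0.00963), where the second number is the limma adjusted p. Hbb-bs belongs to the beta-globin family of near-identical genes, so its value is uncertain. Tuba4a was listed at 568, 548 and 682 in P14 wildtype and at 142, 0 and 0 in libraries labelled knockout (limma adjusted p = 0.0445). Gdf1 was listed at 182, 33.7 and 79.0 in P14 wildtype and at 0 in the 3 libraries labelled knockout (limma adjusted p = 0.00185), and its reads can come from the overlapping gene Cers1.

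In all, 1276 of 14097 genes passed at P14, 202 higher and 1074 lower, and 3833 had an unadjusted p under 0.05. At least a doubling was seen in 9 and at least a halving in 652 of the genes that passed. The groups did not overlap for 4664 genes, against a chance share of 10%. Of 55 lists camera called 33, fry 24, and camera with an estimated correlation 0 (lowest adjusted p = 0.128). The count was 568 without wildtype library 1, 522 without wildtype library 3, 747 without library 2 labelled knockout, 2264 without library 3 labelled knockout, and 722 (16 higher and 706 lower) without the myelin-rich libraries 1 and 2. That last fit leaves 1 library labelled knockout, so its spread comes from wildtype alone and the library is assumed to vary as wildtype does. The 202 genes that were higher became 17 and 13 without wildtype libraries 1 and 3, 28 and 22 without libraries 1 and 2 labelled knockout, and 408 and 881 without wildtype library 2 and library 3 labelled knockout. They were 66 with limma without trend, 602 with the replicate block, 25 and 46 with the male and myelin covariates, and 750 with all 12 libraries in 1 fit. Scaled to the pan-neuronal list, the median gene was at 1.12 and 11825 genes passed, 11619 of them higher, so the directions given are relative to the median gene.

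The last comparison asked whether the effect of the knockout label differs between P14 and P1. It did for 1915 of 14182 genes, 643 with a higher and 1272 with a lower effect at P14 (3902 had an unadjusted p under 0.05). Of 20 pan-neuronal genes, 15 had a lower effect at P14 and 0 a higher one, with a median difference of -1.21 (camera adjusted p = 7.60e-15, but adjusted p = 0.104 with an estimated correlation). Of 21 endothelial genes, 20 had a higher effect at P14, with a median difference of 1.00 (camera adjusted p = 1.34e-11, but adjusted p = 0.212 with an estimated correlation). The effect on Zmiz1 differed by 0.06 (SE 0.11, limma adjusted p = 0.795).

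The differences of potassium channel genes (33 of 57 lower, 0 higher, median -1.27, camera adjusted p = 6.48e-17, but adjusted p = 0.0588 with an estimated correlation) and of neuronal maturation genes (22 of 31 lower, 0 higher, median -1.59, camera adjusted p = 9.75e-17, but adjusted p = 0.0666 with an estimated correlation) were negative. So were those of 17 striatal genes (12 lower, 0 higher, median -1.64, camera adjusted p = 5.33e-10, but adjusted p = 0.0588 with an estimated correlation). Among single genes, Gpr52 (-4.58, limma adjusted p = 0.00563), Tacr1 (-4.43, limma adjusted p = 0.00186), which encodes the substance P receptor, and Gpr149 (-3.95, limma adjusted p = 0.0119) had the lowest differences apart from Eif3j2 and Tuba4a. Gimap9 (3.64, limma adjusted p = 0.00609), Rtp3 (2.97, limma adjusted p = 0.0362) and Tecrl (2.58, limma adjusted p = 0.0382) had the highest apart from Eif3j1 and Tmem254a, for which copies of the gene make the value uncertain. Apart from Tecrl, these genes are at 0 in at least 1 library, so the sizes depend on the pseudocount.

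Across 13405 genes measured at both ages, the log2 fold changes at P1 and P14 had a Pearson correlation of -0.31 and a Spearman correlation of -0.32; genes are not independent replicates, so no p is given. Tbr1, Epha3 and Unc5a fell at both ages, against 2.12 genes for independent lists (Fisher's exact test, two-sided, p = 0.467). Scaled to the pan-neuronal list, Tbr1 and Epha3 were at 0.077 and 0.45 at P14. Lrrc4c, Ptprt, Ripor2 and Trank1 rose at P1 and fell at P14, 4 genes against 1.02 (two-sided Fisher's exact p = 0.0153; Lrrc4c and Ptprt were at 0.32 and 0.34 at P14 when scaled), and Ccdc141 and Sema3c did the reverse, 2 against 0.405 (p = 0.0615, exact). No gene rose at both ages (0 against 0.195). The Fisher p values of these overlaps treat genes as independent and were not adjusted over the overlaps tested. They do not measure replication between animals. Camera called 30 of 55 lists in the difference, fry 27, and camera with an estimated correlation 0 (lowest adjusted p = 0.0588). The count of 1915 was 1209 without P1 wildtype library 3, 1229 and 1274 without P1 libraries 1 and 2 labelled knockout, and 1260 without P14 wildtype library 1. The 643 genes with a higher effect at P14 became 412 and 299 without P1 wildtype libraries 1 and 3, 318 and 320 without P1 libraries 1 and 2 labelled knockout, and 374 with limma without trend. They were 320 and 381 without P14 wildtype libraries 1 and 3, and 423 and 1101 without P14 libraries 2 and 3 labelled knockout.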

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

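The test of the difference between ages was planned, and all tests of explanations in this part were chosen after the results were seen.

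The effect of the knockout label differed between P14 and P1 for 1915 genes, which is why these genes and lists stand here. Gimap9 (3.64), Rtp3 (2.97) and Tecrl (2.58) had a higher log2 effect at P14, and Gpr52 (-4.58), Tacr1 (-4.43) and Gpr149 (-3.95) a lower one. Eif3j1 (limma adjusted p = 3.14e-05), Eif3j2 (3.40e-11), Tuba4a (0.0272) and Tmem254a (0.0343) differed too. All of these but Tecrl are at 0 in some libraries, so their sizes depend on the pseudocount. Camera called 17 lists in opposite directions at the ages and in the difference, although 0 were called with an estimated correlation (lowest adjusted p = 0.0588). Those higher at P1 and lower at P14 were potassium channels (camera adjusted p of the difference = 6.48e-17), neuronal maturation (9.75e-17), pan-neuronal (7.60e-15), presynaptic (2.30e-14), sodium and calcium channels (3.47e-13), ionotropic glutamate receptors (1.68e-12) and GABA and glycine receptors (1.07e-11). They also included striatal (5.33e-10), neuropeptide (1.14e-09), monoamine and acetylcholine receptor (8.81e-09), postsynaptic scaffold (1.43e-08), interneuron (3.94e-07), metabotropic glutamate receptor (8.50e-06), deep-layer (9.17e-06) and oxidative phosphorylation genes (4.64e-05). For 10 of these 15 lists, all but the potassium, sodium and calcium channel, striatal, monoamine and acetylcholine receptor and postsynaptic scaffold lists, the library means of the P1 groups overlapped. Their directions at P14 are those on the deposited scale. Scaled to the pan-neuronal list, the P14 medians of oxidative phosphorylation (1.01), postsynaptic scaffold (0.60) and interneuron genes (0.37) were above 0. So were those of deep-layer (0.24), sodium and calcium channel (0.17) and presynaptic genes (0.16). The medians of the rest of these lists stayed below 0. The difference was not tested under that scaling. Those lower at P1 and higher at P14 were endothelial (1.34e-11) and MHC class I genes (0.00529). Of 100 splits of the libraries within each age, only the real one gave as many as 1915 genes, and the highest of the others was 1762, in a split that kept the true P14 groups.

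Neuronal genes were lower in all 3 P14 libraries labelled knockout. On the deposited scale, a change confined to neurons of the Emx1 lineage is argued against by the pan-glutamatergic minus the interneuron list mean. This difference, which no scaling changes, shifted by -0.049 (SD 0.29 in wildtype and 0.23 in libraries labelled knockout). On that scale such a change needs about -0.86. The need itself depends on the scaling, as the pan-glutamatergic median was 0.18 when scaled to the pan-neuronal list. On other scales the difference therefore does not decide the matter. The interneuron list (median -0.75, or 0.37 when scaled) also holds genes that other neurons use. Dilution by myelin is argued against by library 3 labelled knockout, which has little myelin RNA yet a pan-neuronal mean of -1.11, though this rests on 1 library. With the myelin list mean as a covariate the median of the genes that were lower was -1.09, against -1.18 without it. This adds little, since these genes were chosen from the same libraries and their groups did not overlap, library 3 included. A lower share of neurons of unchanged makeup is not decided. The maturation list mean minus the immature list mean shifted by -1.04 (SD 0.17 in wildtype and 0.03 in libraries labelled knockout). A lower share forbids such a shift only if both lists are equally restricted to neurons. That was not tested, and Nrp1 of the immature list rose. The other cell type lists parted about as often as by chance (4 of 36 pairs, against 3.6). That count does not decide the matter, since the pairs share lists and some differences varied widely. The SD of myelinating oligodendrocyte minus erythroid reached 2.11 in libraries labelled knockout. A lower share as all or part of the fall, a loss of the more mature neurons, and the deletion of Zmiz1 itself stay open. The 10 splits of the P14 libraries are too few for a share under 0.05; 1 of them, the real one, gave as many as 1276 genes and the highest other gave 2.

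Eif3j1 and Eif3j2 were listed at 0 in opposite P1 groups. A switch that follows the genotype is argued against by the P14 wildtype libraries, which have Eif3j2 at 601 or more and Eif3j1 at 0, unlike P1 wildtype. The assignment of reads to 1 member of the pair stays open: each library lists 1 of them at 0, and the P1 group means of the sum were 864 ± 113 and 711 ± 17.1, a ratio of 0.823. However, 87.4% of the 75-base sequences of Eif3j2 but only 37.7% of those of Eif3j1 are shared, so shared reads alone do not account for Eif3j1 at 0 in 9 libraries. Why the P1 wildtype libraries would be counted differently from the other 9 is not given in the sources.

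Neurog2, Tbr1 and Slc17a6, genes of the glutamatergic lineage, fell in P1 libraries labelled knockout. More tissue from outside the cortex stays open: the striatal list had a median of 0.34 and its library means parted the groups, while the upper-layer list had a median of 0.021 with members on both sides of 0 (quartiles -0.23 and 0.27) and the deep-layer list one of 0.18. Fewer dividing cells stay open. The proliferation list showed no fall (median 0.082), but its library means overlapped between the groups (SD 0.21 in wildtype and 0.19 in libraries labelled knockout). With the share of male cells as a covariate, Neurog2 (-1.35), Tbr1 (-0.75) and Slc17a6 (-0.74) still passed. At most 1 of them can have passed with limma without trend, or in 1 fit of all 12 libraries, as each called 1 higher and 1 lower gene. As reported, the uncertain Eif3j1 was also lower and ranked ahead of Neurog2 (limma adjusted p = 4.63e-08 against 0.00913). With the male covariate 100% of the 41 genes kept their direction and at least 0.5 of their log2 fold change, but 16 lost their call. The median SE of these 16 went from 0.102 to 0.116 while their median size stayed at 0.62. This retention is a weak test of sex as the cause. The groups did not overlap for any of the 41 genes, although Y-linked levels in P1 wildtype ran from 0 to 1. A gene that follows sex would hardly have been called. An effect of the Zmiz1 deletion may remain as a hypothesis, untested since the total over the gene does not check the deletion. The 10 splits of the P1 libraries are too few for a share under 0.05: 1 of them, the real one, gave as many as 41 genes and the highest other gave 4.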

How the results depend on the processing

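Of the alternatives, 1 fit of all 12 libraries for the knockout comparisons, limma-voom, the male and myelin covariates, the fit without myelin-rich libraries, pan-neuronal scaling and thinning were chosen after seeing the data. The 41 genes at P1 were 2 with limma without trend, 2 in 1 fit of all 12 libraries, and 6 to 139 on leaving out a library; under TMM scaling, the filters, the pseudocounts and limma-voom 36 to 42 passed, 36 to 41 of them among the 41, and with the male covariate 35, of which 25 were. The 1276 genes at P14 were 787 with the male covariate, 722 without the myelin-rich libraries 1 and 2 labelled knockout (which leaves 1 such library, assumed to vary as the wildtype ones do), 2421 in 1 fit of all 12 libraries, and 522 to 2264 on leaving out a library; the remaining alternatives other than pan-neuronal scaling and the block gave 924 to 1337. The 1915 genes of the difference were 1209 to 2624 on leaving out a library. Fewer libraries lower the power, but the causes of the rises and of the other changes were not tested. Lists called by camera at P1 (24), P14 (33) and in the difference (30) were 0, 0 and 0 with an estimated correlation, and fry called 0 at P1, 24 at P14 and 27 in the difference; leaving out a library gave 19 to 25, 30 to 37 and 26 to 31.

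With the replicate number as a block, 353 genes passed at P1 (166 higher and 187 lower), 1837 at P14 (602 and 1235) and 2307 in the difference (905 and 1402). The same-number correlations of deviations were 0.067, 0.037 and 0.116 at P1 and -0.004, 0.207 and 0.154 at P14. Between libraries of different number they were -0.120 to 0.045 at P1 and -0.235 to 0.106 at P14. The same-number values are mostly higher but overlap these ranges, so whether the numbers pair the libraries stays open.

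Scaling the P14 libraries to the pan-neuronal list moved the median of all genes to 1.12 and gave 11825 genes, of which 1.74% were lower, against 84.2% as deposited; this scaling by construction sets the mean of the pan-neuronal list equal between libraries. Zmiz1 was then at 1.26. Genes named by the rule that passed as deposited or under it, with a negative log2 fold change as deposited and one above 0 under it, were Slc1a2 (0.012), Pcdh8 (0.069), Cdh13 (0.10), Slc6a1 (0.31), Gad1 (0.27), Dkk3 (0.032), Tubb3 (0.58), Crmp1 (0.54), Dpysl5 (0.58), Elavl2 (0.53), Nnat (0.61), Grm4 (0.026), Chrm4 (0.082), Cspg5 (0.14), Atp5g1 (0.65), Atp5g3 (0.77), Ndufs3 (0.79), Ndufb5 (0.78), Tbr1 (0.077), Agap2 (0.22), Bub1b (0.72), Kif11 (0.75), Birc5 (0.76), Kif20a (0.80), Id4 (0.55), Pax6 (0.72), Sox2 (0.76), Nr4a2 (0.56), Cadm3 (0.14), Nrxn2 (0.35), Slitrk1 (0.20) and Lmo4 (0.21). Relative to the median of all genes, the medians of myelinating oligodendrocyte (2.75), oligodendrocyte precursor (1.67) and oxidative phosphorylation genes (1.01) kept their side. Camera's direction, which rests on t statistics, turned for these lists without a call (camera adjusted p = 0.213, 0.631 and 0.1005). Without the 2 myelin-rich libraries, cholesterol synthesis (0.193), myelinating oligodendrocyte (0.542), oligodendrocyte precursor (0.792) and proliferation genes (0.0246) turned, and with the myelin covariate proliferation genes did (0.0230). Over all pairs of a named gene and an alternative, the call was lost in 164 at P1, 236 at P14 and 76 in the difference, and gained in 74, 117 and 22, with no reversal at P1 or in the difference. All gene reversals at P14 came from pan-neuronal scaling, which was run for P14 only. The myelin covariate and the fit without myelin-rich libraries were also run for P14 only. The absence of reversals at P1 and in the difference is therefore no measure of stability. The alternatives for P14 against P1 wildtype were not run, since that comparison was not tested. Approximate depths of 3.20 to 5.66 M reads limit low genes in the P14 libraries labelled knockout.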

Other observations

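The tests in this part on chromosomes, on sequence near Emx1 and on maturation against immature genes were chosen after the results were seen; the gene lists were fixed beforehand.

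Cell adhesion genes were also lower in P14 libraries labelled knockout. Of 39 synaptic adhesion genes, 17 fell and 0 rose over all genes tested, and 25 fell adjusted over the list alone, with a median of -0.68, or 0.44 when scaled to the pan-neuronal list (camera adjusted p = 3.66e-08, but adjusted p = 0.128 with an estimated correlation). Nrxn1, a presynaptic adhesion gene, fell by 1.18 on the log2 scale (limma adjusted p = 0.00311). Of 21 Eph and ephrin genes, 6 fell and 1 rose, and 9 fell and 2 rose adjusted over the list alone, with a median of -0.47, or 0.66 when scaled (camera adjusted p = 0.00704, but adjusted p = 0.294 with an estimated correlation); Epha5 was at -1.37 (limma adjusted p = 0.00410). Among 26 cadherins, 7 fell and 0 rose, and 10 fell and 2 rose adjusted over the list alone (median -0.21, or 0.90 when scaled; camera adjusted p = 0.0145, but adjusted p = 0.172 with an estimated correlation), Cdh9 among them at -2.39 (limma adjusted p = 0.00555). Clustered protocadherins were not called (median -0.17, camera adjusted p = 0.188).

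The 80 ribosomal protein genes had medians of 0.13 at P1 and 0.17 at P14, with 0 passing over all genes and 1 and 0 adjusted over the list alone (camera adjusted p = 7.60e-05 and 1.09e-07, but adjusted p = 0.786 and 0.533 with an estimated correlation). Of 19 meningeal fibroblast genes at P1, 0 passed either way and the median was 0.65 (camera adjusted p = 0.00140, but adjusted p = 0.647 with an estimated correlation). Endothelial genes moved by nearly the same amount each, with quartiles of -0.52 and -0.43 at P1 and 0.50 and 0.56 at P14, whereas the quartiles of the pan-neuronal list at P14 were -1.69 and -0.54. Chromatin remodelling genes of the BAF complex had medians of 0.01 at P1 and -0.08 at P14 and were not called (camera adjusted p = 0.995 and 0.349).

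Neuronal genes did not fall equally at P14. The mean of the maturation list minus that of the immature list was -1.01, -1.03 and -1.07 in the libraries labelled knockout and -0.13, -0.06 and 0.19 in wildtype. The shift of -1.04 exceeds the SD of 0.17 in wildtype and 0.03 in libraries labelled knockout, which argues against a single equal fall of neuronal genes. Neurons that are less mature, or a loss of the more mature ones, may underlie this shift, and these were not told apart. A lower share of neurons could also give it if the immature list is less restricted to neurons, which was not tested.

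The genes that passed at P1 were not spread evenly over the chromosomes. Chromosome 2 held 11 of them, against 3.29 by its share of the genes tested, with a lowest adjusted p over the chromosomes of 0.00562 (two-sided Fisher's exact test). These 11 were Ccdc141, Eif3j1, Lhx2, Lhx6, Lrrc4c, Osbpl6, Prex1, Ptprt, Tbr1, Tox2 and Tyro3. The test treats genes as independent, and the value of Eif3j1 is uncertain. The genes that passed at P1 also numbered 6 to 139 on leaving out a library, and the chromosomes were not tested on those sets. Segregating strain differences on chromosome 2 could give such clustering, and no variant data were at hand to test this. Near Emx1, where Cre is expressed, 2 of 182 genes within 20 Mb passed (1.10%: Foxp1 and Frmd4b), against 0.287% elsewhere (two-sided Fisher's exact p = 0.102), so variants carried along with the Cre allele cannot be told apart from chance with 2 genes.

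The libraries differed in sex-linked genes. Levels of 4 Y-linked genes relative to the highest library of the table were 0.000298, 1 and 0 in P1 wildtype, 0.486, 0.474 and 0.962 in P1 libraries labelled knockout, 0.863, 0.866 and 0.838 in P14 wildtype, and 1, 0 and 0.859 in P14 libraries labelled knockout. Libraries 1 and 2 of the P1 group labelled knockout had middle levels of both Y-linked genes and Xist (17102 and 23140 normalised counts, against 42591 and 49004 in P1 wildtype libraries 1 and 3). The share of haemoglobin in the normalised counts was 0.258% to 1.04% at P1 and 3.18% to 5.62% at P14.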
